A study of Mus musculus with 6 samples.

How the data were processed

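The samples were 6 arrays of total RNA from 1 mouse embryonic stem cell line, 3 after CHIR99021 and 3 after XAV939, and each array was placed in its group by its treatment label. Per the labels' protocols, RNA was isolated with TRIzol and column purification, and 300 ng was labelled with the Affymetrix GeneChip whole-transcript kits. The deposited table holds log2 expression values per probe set, made by the authors with RMA, which is named in the submitters' processing notes. The RMA version and genome build are not given in the sources used here. RMA corrects the background, normalises between arrays by quantiles and summarises the probes of each probe set, so values are comparable between arrays for a given probe set, and differences of weakly expressed genes tend to be compressed. Levels of different genes were not compared as amounts. Scanner files were not used here, so no detection call was made and no scan date or batch was tested. For arrays, the number of arrays limits the precision.

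The table held 34760 probe sets. Gene names came from the platform annotation, which listed 22961 of them. Of these, 21640 named 1 gene and 1321 named several, and the latter were not named or tested as genes. The remaining 11799 probe sets have no gene name here and were tested without one. By Entrez identifier, 21553 of the single-gene probe sets matched the RefSeq gene table and 0 symbols needed an update. Each gene was represented by the probe set with the highest mean over the 6 arrays, which gave 19937 genes. More than 1 probe set was present for 954 genes, and the probe sets of 0 of them were called in opposite directions.

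Treatments were compared with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3 on the deposited log2 values without further normalisation or filtering. The contrast was CHIR99021 minus XAV939 over all 6 arrays, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The residual degrees of freedom were 4 and the prior degrees of freedom 6.15. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1, so none was used for single genes. The median log2 difference of all genes was 0.0066, and with 1 array left out it was between -0.00077 (without CHIR99021 replicate 3) and 0.012 (without CHIR99021 replicate 1), with 0.011 without XAV939 replicate 1 and 0.0028 without XAV939 replicate 2. Plots were drawn with matplotlib 3.10.9.

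The procedure was tested on simulated data for this contrast, with 19937 genes and 5 simulations. It called 74.4% of genes planted with a log2 difference of 0.3, 99.2% at 0.5 and 100% at 1 and at 1.5, and 46 of 98685 unchanged genes. The simulated noise was independent between genes and equal between arrays, and fewer genes were planted than were called in the real data. Under these settings changes below a log2 difference of about 0.3 would often be missed. The shares may differ in the real data.

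Gene lists, 4 primary and 24 others, were fixed before the data were examined. They held 525 different genes, of which 484 were measured. Lists were tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists. Camera with a correlation estimated from the residuals, and fry, which asks whether a list moves one way on balance, were run beside it. Member counts are given after adjustment over all genes and, in those words, adjusted over the list alone. Lists share genes and are not independent: genes also held by another list numbered 8 of 15 in the BMP list, 7 of 12 in the Nodal/activin list, 7 of 24 in the streak list, 7 of 17 in the trophectoderm list, 6 of 16 in the LIF/STAT3 list, 5 of 23 in the Wnt target list, 5 of 22 in the naive list, 4 of 17 in the junction list, 3 of 15 in the primed list, 3 of 17 in the FGF/ERK list, and 2 or fewer in the others.

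The genes named in the text followed a rule fixed before the data were examined. It took the 12 genes with the largest log2 difference in each direction among those past the threshold whose treatments did not overlap, leaving out predicted genes (1 higher and 0 lower were skipped). It took 15 genes whatever their values, Axin2, Sp5, Lef1, Cdx1, Cdx2, Nanog, Esrrb, Klf2, Pou5f1, Sox2, Ctnnb1, Tcf7l1, Myc and Ccnd1 among them, of which 14 had a value, and 1 further always-named gene was not analysed here. From each list it took up to 4 members with the smallest p among those past the threshold, or the 2 with the smallest p where none passed. This named 120 genes, of which 113 passed. Where 5 or fewer members of a list passed in a direction, all of them are named, and 27 genes named for that reason alone were chosen after their values were seen, as were Krt8, Tfap2c and Eomes in the trophectoderm list, the genes of the plot of levels per array and the neighbouring genes in the closing observations.

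Alternatives fixed in advance were centring each array on its median, quantile normalisation of the deposited values, leaving out genes below the 30th or the 50th percentile of the levels of all probe sets, the mean of a gene's probe sets, a trended and robust prior, array weights, the replicate number as a block, leaving out each array in turn, testing all probe sets, a threshold of 0.01 and ordinary least squares. For lists the prior in camera was trended but not robust. Leaving out both CHIR99021 replicate 3 and XAV939 replicate 1, the arrays that stood farthest from their groups, was added after seeing the data. Splits of the 6 arrays into 3 and 3 were refitted in all 10 ways. The order of genes along chromosomes was taken from the RefSeq table of assembly GRCm38.p6, for which genes neighbour each other only.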

Results

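Transcript levels were measured on 6 one-colour Affymetrix arrays of mouse embryonic stem cells grown in serum with LIF, a cytokine that keeps these cells undifferentiated. The cells were a V6.5 line in which the endogenous Ctnnb1 gene, encoding β-catenin, carried a biotin-acceptor and FLAG tag, in cells that also expressed the biotin ligase BirA. Cultures were maintained on feeder cells, which are growth-arrested fibroblasts in common practice. Of the 6 arrays, 3 were of cells given CHIR99021, an inhibitor of the kinase GSK3 that stabilises β-catenin, and 3 were of cells given XAV939, a tankyrase inhibitor that stabilises Axin and lowers β-catenin, each for 24 h. CHIR99021 was used at 3 µM. The XAV939 dose was given as 3 µM in the sample labels and as 1 µM in the treatment protocol. The comparison addressed the transcriptional response of the cells to opposite settings of the Wnt pathway. With no untreated arrays analysed here, a difference was not assigned to either compound. The labels did not say whether replicates were separate cultures and p-values measured only the spread between these arrays.

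The arrays had closely similar value distributions, with medians between 5.67 and 5.71 on the log2 scale. Pearson correlations across genes were 0.997 to 0.999 between arrays of one treatment and 0.994 to 0.995 between treatments. The first principal component held 60.5% of the variance and separated the treatments. The next held 17.5% and set XAV939 replicate 1 apart from replicates 2 and 3. CHIR99021 replicate 3 was, to a smaller extent, the array of its group that correlated least with the others.

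Axin2 (probe set 10382228), a negative-feedback target of β-catenin, rose 3.75-fold, from a log2 level of 5.57 ± 0.19 (SD, n = 3) to 7.48 ± 0.06 (SD, n = 3). Cdx2 and Cdx1, homeobox genes of posterior identity, rose 3.09-fold and 3.08-fold, with log2 differences of 1.63 ± 0.10 and 1.62 ± 0.18 (SE). Mixl1, a homeobox gene of the primitive streak, rose 2.82-fold (1.50 ± 0.10, SE). Otx2, a transcription factor of anterior neural tissue and of the primed epiblast, the state that follows naive pluripotency, was 4.40-fold lower with CHIR99021 (-2.14 ± 0.09, SE), and Dnmt3a, a de novo DNA methyltransferase, was 2.84-fold lower (-1.50 ± 0.07, SE). All differences are CHIR99021 minus XAV939 in log2 units with the standard error of the limma fit, from 3 arrays per treatment.

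Of 19937 genes tested, 1924 (9.65%) passed an adjusted p of 0.05 in limma's moderated test, 1058 of them higher and 866 lower with CHIR99021. Most changes were small. The median absolute log2 difference of the changed genes was 0.36, or 1.28-fold, and 74 genes differed at least 2-fold, 50 higher and 24 lower. The values of the treatments did not overlap for 5010 genes (25.1%, where chance gives 10%), among them 1920 of the 1924. Without CHIR99021 replicate 2 the count of changed genes was 1254 and that of lower genes 528, and without CHIR99021 replicate 1 that of lower genes was 573.

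The largest rise among named genes was that of Il24, a cytokine of the interleukin-10 family, at 2.18 ± 0.06 (4.53-fold, adjusted p = 5.00e-08). Epp13 rose by 1.91 ± 0.06, Pglyrp1, a peptidoglycan recognition protein, by 1.75 ± 0.06, and Pmp22, a membrane protein of peripheral myelin, by 1.68 ± 0.07. Plagl1, an imprinted zinc finger gene, rose by 1.62 ± 0.07. Grsf1, an RNA-binding protein of mitochondrial RNA granules, rose by 1.61 ± 0.06. Wnt5a, a Wnt ligand that acts largely without β-catenin, rose by 1.59 ± 0.07, and Dsc2, a desmosomal cadherin, by 1.50 ± 0.06.

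In the other direction, Enpp3, a cell-surface nucleotide pyrophosphatase, was 6.93-fold lower with CHIR99021 (-2.79 ± 0.07, adjusted p = 2.21e-08), and Slc27a2, a very long-chain acyl-CoA synthetase, was 5.03-fold lower (-2.33 ± 0.06). Pim2, a serine/threonine kinase, fell by 2.18 and Car4, a carbonic anhydrase, fell by 1.67. The endocytic receptor gene Lrp2 fell by 1.60, and Lefty1, an antagonist of Nodal signalling, fell by 1.49. The semaphorin Sema3e fell by 1.48, Tmem54 fell by 1.34, the helix-loop-helix gene Tcfl5 fell by 1.30 and Smarca1, a chromatin remodelling ATPase, fell by 1.26. These 24 genes, 12 in each direction, kept their direction and their call in the 15 alternatives run for single genes, which include leaving out each array but not the test of all probe sets, the threshold of 0.01 or ordinary least squares. They were chosen from these same arrays for large differences without overlap, so leaving out an array could not turn their direction.

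**Figure D1:**
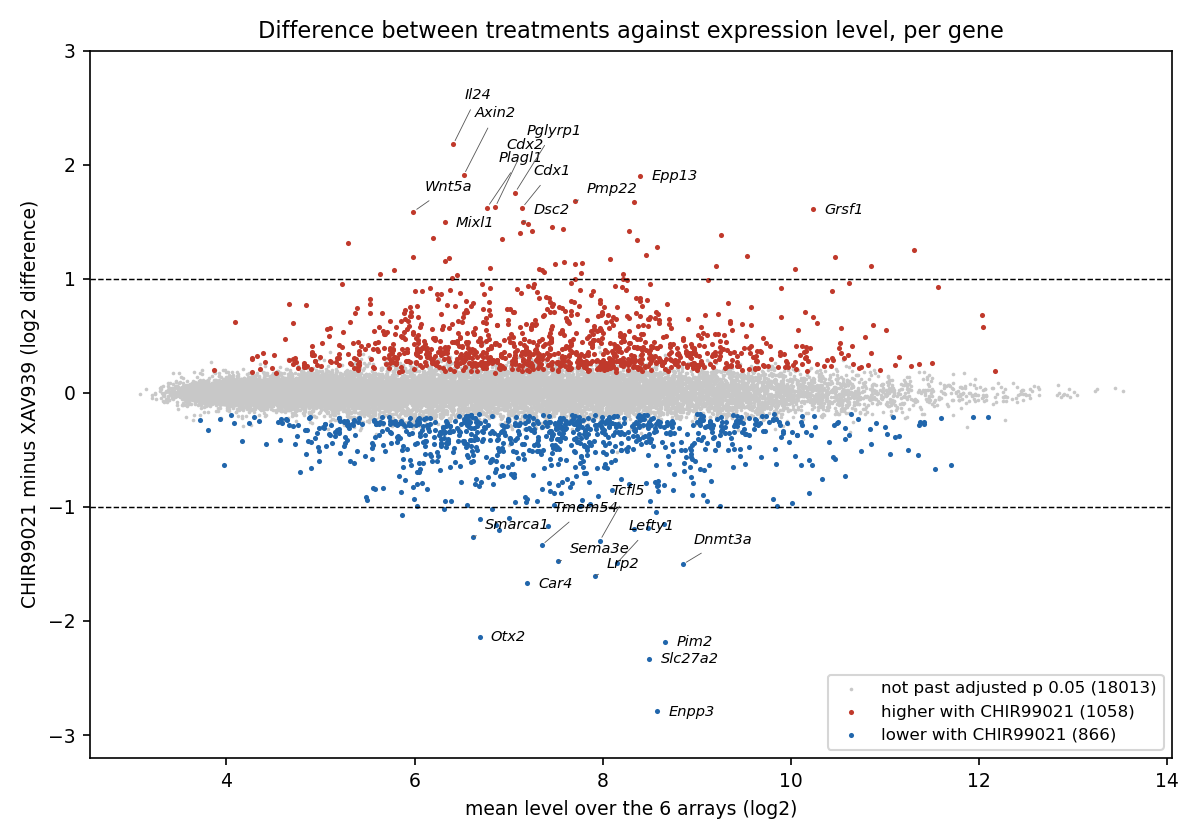
Log2 difference between CHIR99021 and XAV939 against the mean log2 level over the 6 arrays, 1 point per gene. Red points are the 1058 genes higher and blue points the 866 genes lower with CHIR99021 at adjusted p under 0.05, grey points are the other genes, dashed lines mark a log2 difference of 1 in either direction, and the 12 named genes with the largest difference each way are labelled, from Enpp3 at -2.79 to Il24 at 2.18.

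Among 23 measured Wnt/β-catenin target genes, 10 rose, 2 fell and 11 did not pass. Beside Axin2, Cdx1 and Cdx2, Sp5, a transcription factor directly induced by β-catenin, rose by 1.35 ± 0.14 (adjusted p = 1.34e-04), Tnfrsf19 by 0.79 ± 0.06, and Lef1, a DNA-binding partner of β-catenin, by 0.69 ± 0.06. Those that fell were Fzd7, a Wnt receptor (-1.04 ± 0.08), and Myc, a growth-promoting transcription factor (-0.68 ± 0.07). Ccnd1, the cyclin D1 gene, differed by 0.11 ± 0.05 (adjusted p = 0.266). Adjusted over the list alone, 11 were higher and 4 lower. The list was higher than other genes in camera, a gene set test of limma used with a preset inter-gene correlation of 0.01 (adjusted p = 1.37e-05). The call was lost at adjusted p = 0.164 with an estimated correlation.

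Genes for components of the Wnt pathway moved both ways, with 5 of 34 higher, 4 lower and 25 not past the threshold, and the counts were the same adjusted over the list alone. Wls, needed for secretion of Wnt ligands, rose by 1.40 ± 0.12, the receptor gene Fzd10 by 1.09 ± 0.10, the receptor kinase gene Ror2 by 0.43 ± 0.06, Wnt6 by 0.34 ± 0.06 and Porcn, the acyltransferase of Wnt ligands, by 0.32 ± 0.06. Tcf7l1, a repressor at Wnt target genes, fell by 0.79, Fzd8 fell by 0.45, the secreted antagonist Sfrp1 fell by 0.26 and Tcf7l2 fell by 0.25. Ctnnb1 itself had a log2 level of 11.07 ± 0.01 (SD, n = 3) with CHIR99021 and 11.05 ± 0.07 (SD, n = 3) with XAV939, a difference of 0.018 ± 0.054. The list as a whole did not pass (camera adjusted p = 0.741). Its mean of 0.041 was above 0 while its median was -4.9e-06 (0.0025 without CHIR99021 replicate 2) and camera's direction was down. The call of Tcf7l2 was lost without CHIR99021 replicate 1 or 2 or XAV939 replicate 2 or 3 (adjusted p = 0.0688 to 0.114), and that of Sfrp1 without CHIR99021 replicate 2 (0.0545).

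Primitive streak and mesendoderm genes, active in cells leaving the epiblast at gastrulation, rose more often than they fell, with 10 of 24 past the threshold upward, 1 downward and 13 not past. Mixl1 was followed by Cyp26a1, a retinoic acid-degrading enzyme, at 1.19 ± 0.12 (2.29-fold) and by Eomes, a T-box gene of the streak and trophectoderm, at 1.18 ± 0.08 (2.27-fold). Nodal, the ligand that drives mesendoderm formation, was the member that fell (-0.78 ± 0.06). Of its members, 11 were higher and 1 lower when adjusted over the list alone. The list was higher in camera (adjusted p = 8.14e-06), which was lost with adjusted p = 0.185 with an estimated correlation.

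Naive pluripotency genes, characteristic of the pre-implantation epiblast, were higher in 12 of 22 cases, lower in 2 and not past the threshold in 8. Tfcp2l1, a transcription factor of naive cells, rose 2.61-fold (1.38 ± 0.05, adjusted p = 1.81e-07), Tbx3 by 0.93 ± 0.06, Klf4 by 0.81 ± 0.07 and Nr5a2 by 0.69 ± 0.05. Esrrb, an orphan nuclear receptor repressed by Tcf7l1, rose by 0.60 ± 0.06 and Nanog by 0.49 ± 0.05. Klf2 differed by 0.15 ± 0.09 (adjusted p = 0.399), a value that depended on single arrays, with 0.086 without CHIR99021 replicate 3, 0.10 without XAV939 replicate 2 and 0.25 without XAV939 replicate 1 (adjusted p = 0.0642 to 0.724 over the alternatives). Dppa2 fell by 0.56 and Fgf4, the growth factor that promotes exit from naive pluripotency, fell by 0.38. Adjusted over the list alone, 14 were higher and 3 lower. Camera placed the list higher (adjusted p = 6.30e-07), a call lost at adjusted p = 0.134 with an estimated correlation.

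All 15 measured primed epiblast genes had a negative difference, and 11 of them fell, with a list median of -0.68. Pim2, Otx2 and Dnmt3a had the largest differences, and Dnmt3b, a de novo methyltransferase of the epiblast, fell by 0.96. Of its members, 14 were lower when adjusted over the list alone. The list had the smallest camera p of all lists (adjusted p = 5.07e-20), a call lost in camera at adjusted p = 0.0555 with an estimated correlation.

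Core pluripotency genes, shared by naive and primed cells, fell in 9 of 13 cases and rose in none. The members with the smallest p were Utf1 (-0.67 ± 0.09), Tdgf1, a co-receptor of Nodal (-0.63 ± 0.07), Sall1 (-0.63 ± 0.07) and L1td1 (-0.36 ± 0.06). Pou5f1, encoding OCT4, differed by -0.19 ± 0.06 and did not pass (adjusted p = 0.115), although without CHIR99021 replicate 3 its adjusted p was 0.0396 (0.0336 to 0.366 over the alternatives). Sox2 was at 10.98 ± 0.03 with CHIR99021 and 10.98 ± 0.05 with XAV939 (SD, n = 3), a difference of 0.0057 ± 0.0520. Adjusted over the list alone, 10 were lower. The list was lower in camera (adjusted p = 9.68e-09), with adjusted p = 0.0555 with an estimated correlation.

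**Figure D2:**
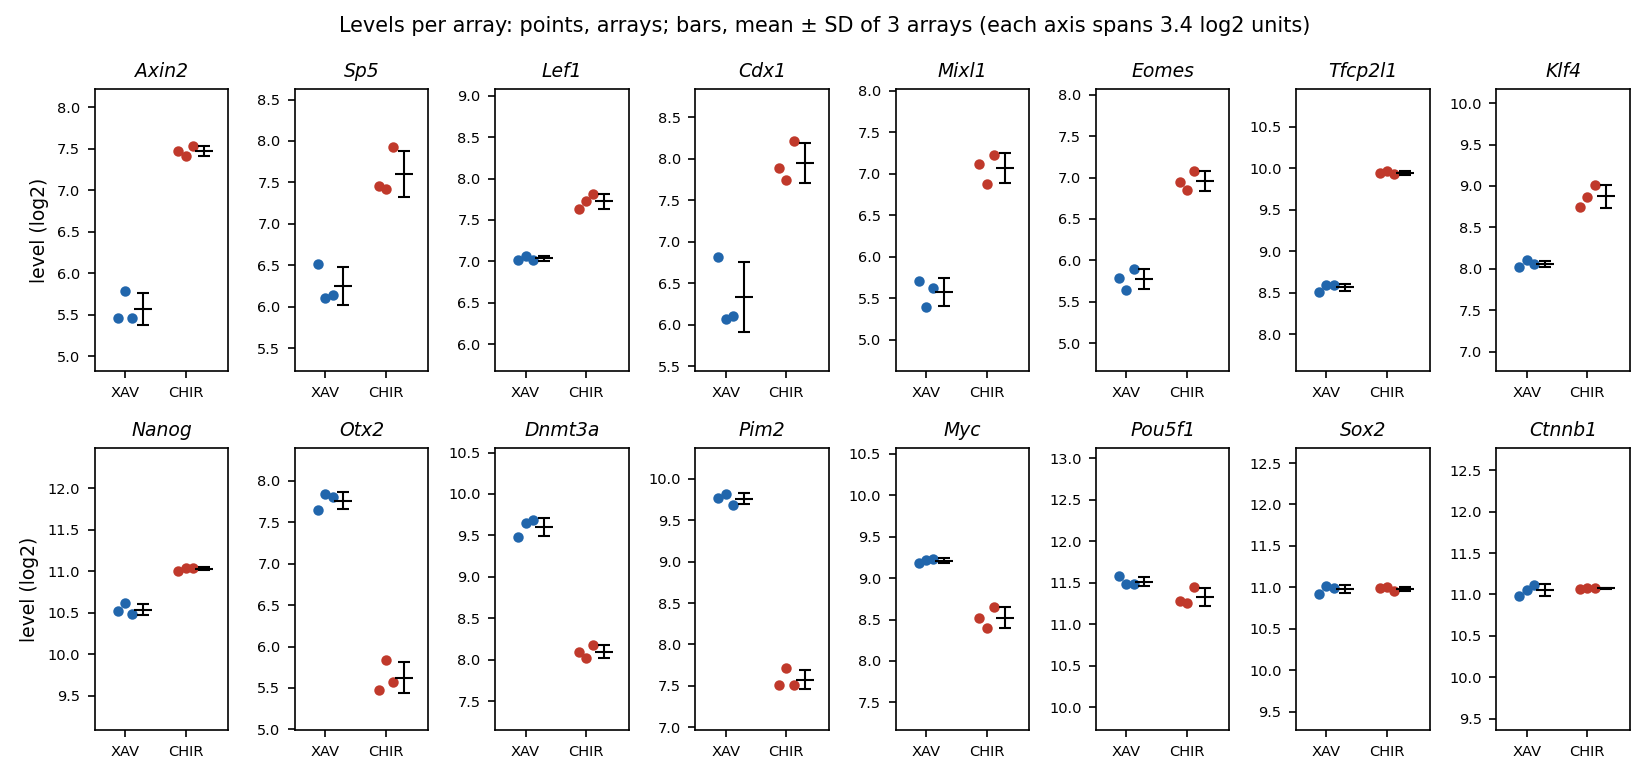
Log2 level on each array of 16 genes, chosen from those named in the text, after XAV939 (blue) and CHIR99021 (red), with points for arrays, bars for the mean ± SD of 3 arrays and axes of equal span. Axin2, Mixl1 and Tfcp2l1 lay higher on each CHIR99021 array than on any XAV939 array, Otx2, Dnmt3a and Pim2 lay lower, and the values of Sox2 and Ctnnb1 overlapped.

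Among neuroectoderm genes, 4 of 19 fell, none rose and 15 did not pass. Nes, an intermediate filament of neural progenitors (-0.82 ± 0.06), Neurod1, a proneural transcription factor (-0.69 ± 0.10), the neuronal tubulin gene Tubb3 (-0.61 ± 0.12) and Pax6, a neural patterning gene (-0.60 ± 0.06), were lower with CHIR99021. The same number, 4, passed adjusted over the list alone. Pax6 and Neurod1 lay below the median level of all probe sets, with mean log2 levels of 5.31 and 4.78. The list was lower in camera (adjusted p = 0.0137) and was not called at adjusted p = 0.411 with an estimated correlation. The call depended on XAV939 replicate 1, without which the adjusted p was 0.189, and on genes of low level, since without those below the 50th percentile it was 0.137 (0.00133 to 0.411 over the alternatives).

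Of 17 trophectoderm genes, 7 rose, none fell and 10 did not pass. The simple-epithelium keratins Krt18 (1.19 ± 0.07), Krt19 (1.08 ± 0.06), Krt8 (0.93 ± 0.07) and Krt7 (0.88 ± 0.06) were 4 of the 7, with Cdx2, Eomes and Tfap2c, and 7 of the 17 genes also stood in another list. Of its members, 9 were higher and 1 lower when adjusted over the list alone. The list was higher in camera (adjusted p = 6.30e-07), with adjusted p = 0.185 with an estimated correlation.

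Primitive endoderm genes did not pass as a list (camera adjusted p = 0.0717), with 3 of 22 higher, 1 lower and 18 not past, against 4 and 1 adjusted over the list alone. Cited1, a transcriptional co-activator, rose by 0.83 ± 0.13, the basement membrane genes Sparc and Lama1 by 0.27 ± 0.06 and 0.26 ± 0.05, and Dab2, an endocytic adaptor, fell by 0.35. Without XAV939 replicate 1 the list was called at adjusted p = 0.00615 (0.00311 to 0.492 over the alternatives). The call of Dab2 was lost without CHIR99021 replicate 1 or 2 or XAV939 replicate 1 or 2 (0.0673 to 0.126), and its other probe set gave -0.087.

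Germ cell genes fell more often than they rose, with 1 of 18 higher, 5 lower and 12 not past the threshold. Nanos3, an RNA-binding protein of primordial germ cells, rose by 0.66 ± 0.05. Rhox9 (-0.62), Mael, a factor of transposon silencing (-0.51), the synaptonemal gene Sycp3 (-0.45), Ddx4, an RNA helicase of germ cells (-0.39), and Stra8, a meiotic entry gene (-0.30), were lower. Mael, Stra8 and Sycp3 lay below the median level of all probe sets, with mean log2 levels of 5.39, 4.99 and 4.42. Adjusted over the list alone, 1 was higher and 7 lower. The list was lower in camera (adjusted p = 0.00165), a call lost at adjusted p = 0.134 with an estimated correlation and at 0.205 without genes below the 50th percentile of level (from 8.27e-04 over the alternatives). Sycp3 passed only with particular arrays: without CHIR99021 replicate 1 or 2 or XAV939 replicate 2 or 3 its adjusted p was 0.0563 to 0.0625.

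Genes of the 2-cell-like state were represented by 9 members, of which 7 lay below the median level, and none passed by limma in either count, over all genes or adjusted over the list alone. The smallest p values were those of Usp17ld (0.22 ± 0.11, unadjusted p = 0.0684) and Usp17lc (0.13 ± 0.07, unadjusted p = 0.0757). No member had an unadjusted p under 0.05, and the list did not pass (camera adjusted p = 0.364, fry adjusted p = 0.254). Without CHIR99021 replicate 3, Usp17ld differed by 0.35 with an adjusted p of 0.0413, and without CHIR99021 replicate 2 by 0.14 (adjusted p up to 0.666 in the other alternatives).

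Hox genes, which pattern the body axis, rose in 3 of 20 cases and fell in none. The members that rose were Hoxd9 (0.42 ± 0.06), Hoxd8 (0.35 ± 0.05) and Hoxd4 (0.32 ± 0.06), all of the HoxD cluster. Of the list's members, 4 were higher when adjusted over the list alone. Hoxd8 had a mean log2 level of 4.39, below the median of all probe sets. Camera placed the list higher (adjusted p = 0.00208), with adjusted p = 0.277 with an estimated correlation, and 13 of its 20 members lay below the median level of all probe sets. Without XAV939 replicate 1, 6 of the 20 rose, as they did without both this array and CHIR99021 replicate 3, where the list median went from 0.072 to 0.14. It was 0.13 without XAV939 replicate 1 alone and 0.11 without CHIR99021 replicate 1.

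Genes of mesenchymal cells and of epithelial junctions moved in opposite directions within their lists. Of 14 epithelial-mesenchymal transition genes, 4 rose, 1 fell and 9 did not pass. Vim, the intermediate filament of mesenchymal cells, rose 2.16-fold (1.11 ± 0.06), fibronectin (Fn1) by 0.97 ± 0.05, N-cadherin (Cdh2) by 0.95 ± 0.06 and Tgfb1 by 0.81 ± 0.08, while the metalloproteinase gene Mmp2 fell by 0.39. The counts were the same adjusted over the list alone. The list was higher in camera (adjusted p = 0.00134), with adjusted p = 0.227 with an estimated correlation.

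Markers of feeder fibroblasts moved beside them. Of 24 such genes, 7 rose, 1 (Mmp2) fell and 16 did not pass, the same counts as adjusted over the list alone. Col1a1, the main chain of type I collagen, rose by 1.05 ± 0.05, the smooth muscle genes Tagln and Acta2 by 0.67 ± 0.07 and 0.35 ± 0.05, and Col1a2 by 0.40 ± 0.06. Tagln was at 10.23 with CHIR99021 and 9.56 with XAV939. Camera placed the list higher (adjusted p = 0.00613), with adjusted p = 0.227 with an estimated correlation. Of the 24 genes, 14 lay above the median level of all probe sets and 2 stood in another list.

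Epithelial junction genes were higher in 4 of 17 cases, lower in 5 and not past the threshold in 8. Krt18, Krt8, the tight junction gene Cldn4 (0.71 ± 0.06) and desmoplakin (Dsp, 0.60 ± 0.07) rose. Rab25, a small GTPase of epithelial cells, fell by 0.87. The epithelial splicing regulator Esrp1 (-0.78), Epcam (-0.56), the epithelial transcription factor Grhl2 (-0.40) and E-cadherin (Cdh1, -0.26) were lower as well. Adjusted over the list alone, 4 were higher and 8 lower. The list did not pass (camera adjusted p = 0.257), and its mean of 0.014 was positive while its median was -0.071 (-0.044 without CHIR99021 replicate 1).

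Readouts of other signalling pathways were mixed. Of 15 BMP target genes, 6 rose, 1 fell and 8 did not pass. The ligand gene Bmp4 rose 2.17-fold (1.12 ± 0.05), the homeobox gene Msx1 by 0.81 ± 0.09 and Id3, an inhibitor of helix-loop-helix factors, by 0.63 ± 0.07, while Id2 fell by 0.47. Of its members, 8 were higher and 2 lower when adjusted over the list alone. The list was higher in camera (adjusted p = 0.00334), with adjusted p = 0.227 with an estimated correlation, and 8 of its 15 genes also stood in another list.

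Nodal/activin target genes were divided, with 4 of 12 higher, 5 lower and 3 not past, and 4 and 6 adjusted over the list alone. Lefty1, Skil, a SMAD co-repressor (-0.89 ± 0.07), Nodal, Tdgf1 and Gdf3 (-0.30 ± 0.05) were lower. Bmp4, Lefty2 (0.41 ± 0.07), the inhibitory Smad7 (0.37 ± 0.07) and Pmepa1 (0.28 ± 0.08) were higher. The list did not pass in camera (adjusted p = 0.0689) and passed in fry, which does not compare it with other genes (adjusted p = 0.00250). It also passed in camera with a trended prior (0.0486, up to 0.227 in the other alternatives). The call of Pmepa1 was lost with any 1 array left out except CHIR99021 replicate 2 (adjusted p = 0.0642 to 0.154).

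LIF/STAT3 target genes, which respond to the cytokine in the medium, were higher in 3 of 16 cases, lower in 2 and not past in 11, and 5 and 3 passed adjusted over the list alone. Tfcp2l1, Klf4 and the homeobox gene Gbx2 (0.33 ± 0.08) rose. The kinase gene Pim1 fell by 0.28 and the LIF receptor gene Lifr fell by 0.21. The list did not pass (camera adjusted p = 0.0725), but its adjusted p was 0.0444 without CHIR99021 replicate 1, 0.0424 without CHIR99021 replicate 2, 0.0341 without XAV939 replicate 1 and 0.0178 in fry (up to 0.486 in the other alternatives). Of these members, Gbx2 lost its call without CHIR99021 replicate 1 or 3 or XAV939 replicate 2 or 3 (0.0597 to 0.112), Pim1 without CHIR99021 replicate 1 or 2 or XAV939 replicate 1 or 3 (0.0521 to 0.113), and Lifr without CHIR99021 replicate 1 or 2 or XAV939 replicate 2 or 3 (0.0965 to 0.165).

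FGF/ERK target genes were higher in 4 of 17 cases, lower in 1 and not past in 12, against 5 and 1 adjusted over the list alone. The phosphatase gene Dusp4 rose by 0.83 ± 0.09, Phlda1 by 0.76 ± 0.12, the ETS factor gene Etv4 by 0.76 ± 0.11 and the feedback inhibitor gene Il17rd by 0.41 ± 0.06, and Myc was the member that fell. The list did not pass (camera adjusted p = 0.156), although without XAV939 replicate 1 the adjusted p was 0.0477 (up to 0.628 in the other alternatives), and without CHIR99021 replicate 3, 2 members fell.

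**Figure D3:**
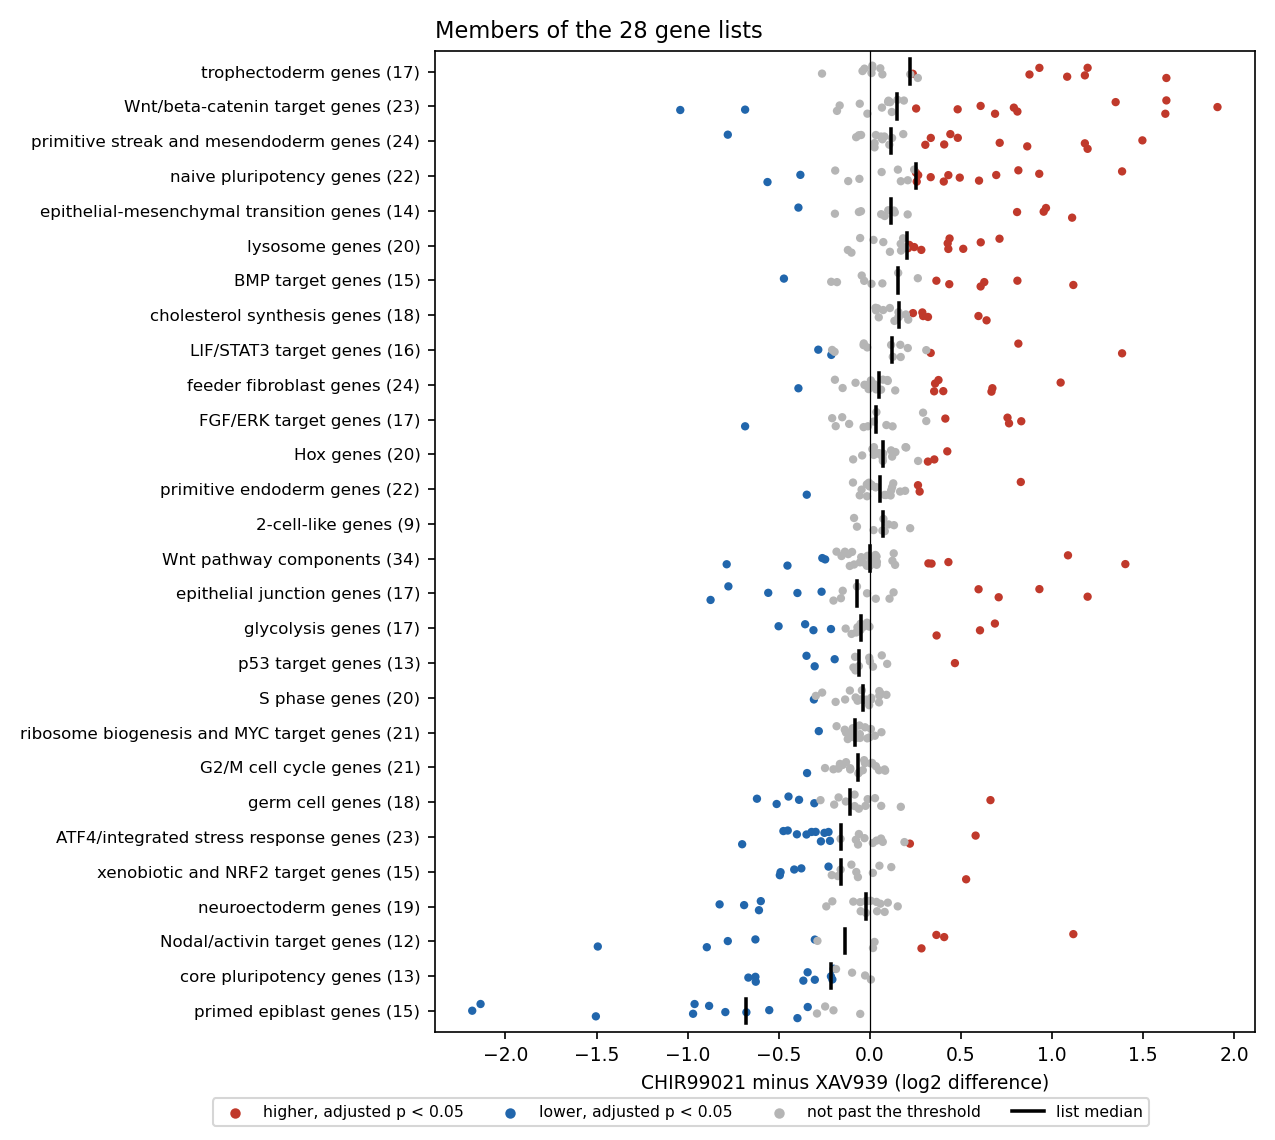
Log2 difference between CHIR99021 and XAV939 of the members of 28 gene lists fixed before the data were examined, ordered by the list mean, with the number of measured genes in brackets. Points are genes, coloured where adjusted p was under 0.05 (red higher, blue lower), and black bars are list medians, from -0.68 for primed epiblast genes to 0.26 for naive pluripotency genes.

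Over all 28 lists, 18 passed an adjusted p of 0.05 in camera with the preset correlation and 17 in fry. With an estimated correlation none passed, with a lowest adjusted p of 0.0555 and 6 lists at an unadjusted p under 0.05. For germ cell genes the estimate was -0.0082, below the preset 0.01, yet camera's unadjusted p rose from 7.09e-04 to 0.0215. This option also refers the test to the 4 residual degrees of freedom. The lost calls therefore cannot be put down to correlation between genes alone. Over all alternatives the estimated correlation gave each of the 18 lists its highest adjusted p, except germ cell genes, which had 0.205 without genes below the 50th percentile of level.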

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

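The tests of feeder content and of leaving out the arrays that stood apart were chosen after the results they test had been seen, while the splits and the removal of an expression-level trend were chosen before.

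Signals were also present in probe sets with no gene name here, which the comparison of genes does not use. Of 11799 such probe sets, 154 passed an adjusted p of 0.05 over all probe sets, 74 higher and 80 lower with CHIR99021, and 10 differed at least 2-fold. The largest log2 difference among them was 3.51 ± 0.14 (SE, 11.4-fold, adjusted p = 1.39e-04), above that of every named gene, and the smallest was -1.72. What these probe sets measure was not analysed here.

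The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1924 changed genes, 1058 higher, 866 lower and 74 at least 2-fold, and the highest of the other splits gave 0 for each, so 1 of the 10 splits reached each real count. Both sides of every other split mix the treatments, which adds any treatment difference to the spread within sides. Low counts there were therefore likely in advance. For gene lists the real split gave 18 past the threshold in camera and the highest of the others 19, so 2 of the 10 splits reached the real count. That other split put CHIR99021 replicates 1 and 3 with XAV939 replicate 1. It still set more CHIR99021 arrays on one side than on the other, so part of any treatment difference remained in it. Its count cannot show how many lists camera calls without a treatment difference.

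Of 24 feeder fibroblast genes, 7 were higher with CHIR99021, 1 was lower and 16 did not pass, with Col1a1 at 1.05. Camera called the list higher (adjusted p = 0.00613), a call lost at adjusted p = 0.227 with an estimated correlation. If a larger share of feeder cells were the whole cause of the Col1a1 rise, other feeder genes would rise by a similar amount unless the stem cells also express them. The median log2 difference of the 13 other feeder genes above the median level was 0.139 (bootstrap interval -0.079 to 0.377), below 0.523, which is Col1a1's difference divided by 2. Yet 9 of the 13 were positive, with 6 past the threshold higher and 1 lower, and their level in stem cells without feeders was not analysed here. A larger feeder share and a response of either cell type to the compounds may each contribute and cannot be told apart here.

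Naive pluripotency genes were higher (12 of 22, with 2 lower) and primed epiblast genes lower (11 of 15) in camera, calls lost with an estimated correlation. The gap between the mean log2 differences of the lists was 1.10 (0.754 to 1.50). Intervals of this gap come from resampling the genes of each list and do not hold the spread between arrays. Without the arrays that stood apart, CHIR99021 replicate 3 and XAV939 replicate 1, the gap was 1.08 (0.722 to 1.49), which argues against these arrays as its cause. The trend of the differences on expression level ran only from -0.015 to 0.016, too small for a gap of this size, and removing it left 1.11 (0.759 to 1.50), which tests nothing further. The gap may reflect the treatments, as a hypothesis found and tested on the same arrays.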

How the results depend on the processing

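Leaving out both arrays that stood apart was chosen after the data were seen, and the other alternatives before. Median centring, quantile normalisation, filters on level, the mean of probe sets and a trended robust prior gave 1851 to 2063 changed genes. Counts moved over 1.5 times with adjusted p under 0.01 (1118 changed, 621 higher, 497 lower), with ordinary least squares (639, 350, 289), with all probe sets tested (698 higher) and with array weights (1409 lower). The first follows from the stricter threshold, and the second from leaving out the moderation of the variances, with its 6.15 prior degrees of freedom. Testing all probe sets counts probe sets in place of genes (1307 changed) and also changes the adjustment and the prior. Which of these mattered was not tested. With array weights 2857 genes changed, the most of any alternative, and the cause was not tested. With any 1 array left out, 1254 (without CHIR99021 replicate 2) to 2247 (without XAV939 replicate 1) genes changed and 528 to 1117 were lower, the same arrays giving the extremes, with 573 lower without CHIR99021 replicate 1. With the replicate number as a block, 1578 genes changed, 1543 of them among the 1924, and 18 lists passed, with fewer members falling among ATF4 targets (6 against 11), core pluripotency (6 against 9), glycolysis (2 against 4), p53 (1 against 3), LIF/STAT3 (1 against 2), primed epiblast (10 against 11) and NRF2 genes (4 against 5), and with the calls of Srm and Dab2 lost, the 1 member each that fell in the ribosome and primitive endoderm lists. With this block fewer members rose among lysosome (8 against 10), naive (11 against 12), Nodal/activin (3 against 4) and glycolysis genes (2 against 3). The same held for cholesterol synthesis genes (5 against 6) and ATF4 targets (1 against 2). Deviations of arrays with the same number correlated at -0.0957, 0.0602 and -0.143, so the numbers were not used to pair arrays.

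With camera's estimated correlation 0 of the other gene lists passed (6 of all lists at an unadjusted p under 0.05, 17 in fry), and the adjusted p was 0.164 for Wnt/β-catenin targets, 0.185 for primitive streak, 0.134 for naive and 0.411 for neuroectoderm genes. Neuroectoderm genes were also not called without genes below the 50th percentile of level (0.137), without both arrays that stood apart (0.106) or in fry (0.0640), and ranged from 0.00133 (without XAV939 replicate 3) to 0.189 (without XAV939 replicate 1). Wnt pathway components turned to higher in fry (0.453). The sign turned for Sox2 with array weights (-0.0041) and without both arrays (-0.0069), and for Ctnnb1 likewise (-1.4e-05 and -0.019). With any 1 array left out Sox2 ranged from -0.022 to 0.024 and Ctnnb1 from -0.017 to 0.050. The causes were not tested. Of 1793 pairs of a rule-named gene and an alternative, 1739 kept direction and call, 43 lost the call, 4 gained it and 7 turned. Sox2 and Ctnnb1 had high mean log2 levels, 10.98 and 11.06. Whether low signal over background limits small differences of other genes was not tested.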

Other observations

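Both tests of neighbouring genes were chosen before their results were seen.

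Of 20 lysosome genes, 10 rose, none fell and 10 did not pass (13 higher adjusted over the list alone), among them Cd63 (0.71 ± 0.11), the cathepsins Ctsb (0.51 ± 0.06) and Ctsl (0.44 ± 0.07), and Npc2 (0.43 ± 0.07), with camera adjusted p = 1.22e-06, and adjusted p = 0.224 with an estimated correlation. All 18 cholesterol synthesis genes had a positive difference and 6 passed (9 adjusted over the list alone), among them Tm7sf2 (0.64 ± 0.06), Hsd17b7 (0.60 ± 0.07), Stard4 (0.29 ± 0.06) and Sc5d (0.24 ± 0.05), with camera adjusted p = 1.22e-06, and adjusted p = 0.185 with an estimated correlation. Of the lysosome genes 6 rose without CHIR99021 replicate 2 or 3, and of the cholesterol synthesis genes 3 rose without CHIR99021 replicate 1 or 2. Sc5d lost its call without any 1 of CHIR99021 replicates 1 to 3 or XAV939 replicate 2 (0.0501 to 0.0674).

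Of 23 ATF4 targets, 2 rose, 11 fell and 10 did not pass, the same counts as adjusted over the list alone. The number that fell was 6 without CHIR99021 replicate 2, XAV939 replicate 2 or XAV939 replicate 3, and 7 without CHIR99021 replicate 3. Asns rose by 0.58 ± 0.06 and Atf3 by 0.22, while Chac1 fell by 0.70, Stc2 fell by 0.45 and Herpud1 fell by 0.40 (camera adjusted p = 1.82e-04, and adjusted p = 0.134 with an estimated correlation). Of 15 xenobiotic and NRF2 targets, 1 rose, 5 fell and 9 did not pass (1 and 8 adjusted over the list alone). Gstm1 rose by 0.53 ± 0.08, and Gclm and Hmox1 each fell by 0.49, Gclc fell by 0.42, Tiparp fell by 0.38 and Slc7a11 fell by 0.23 (camera adjusted p = 6.58e-04, and adjusted p = 0.185 with an estimated correlation). Of 13 p53 targets, Phlda3 rose by 0.47 ± 0.06, Sesn2 fell by 0.35, Eda2r fell by 0.30, Bbc3 fell by 0.19 and 9 did not pass, with the same counts adjusted over the list alone. The list was not called (camera adjusted p = 0.175), but was without XAV939 replicate 1 (0.0341, up to 0.502 in the other alternatives). Bbc3 lost its call with any 1 array left out (0.0552 to 0.138). Atf3 (0.0579 to 0.154), Slc7a11 (0.0804 to 0.186) and Eda2r (0.0639 to 0.111) lost theirs without any 1 array except XAV939 replicate 1. Slc7a11 had a mean log2 level of 4.59, below the median of all probe sets.

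Glycolysis genes went both ways, with 3 of 17 higher, 4 lower and 10 not past, the same counts as adjusted over the list alone. Slc2a3 rose by 0.69 ± 0.06, Aldoc by 0.60 ± 0.09 and Pfkp by 0.37, while Slc16a3 fell by 0.50, Pfkl fell by 0.36, Bnip3 fell by 0.31 and Pfkm fell by 0.21. The list was not called (camera adjusted p = 0.0921), but was without XAV939 replicate 1 (0.0274, up to 0.492 in the other alternatives). Bnip3 (0.0736 to 0.154) and Pfkm (0.102 to 0.147) lost their calls without any 1 array except XAV939 replicate 1, and Pfkp without CHIR99021 replicate 1 or 2 (0.0757 to 0.0988).

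In each of 3 lists of cell growth genes 1 gene fell and none rose, also adjusted over the list alone: Nusap1 of 21 G2/M genes fell by 0.34, Ccne1 of 20 S phase genes fell by 0.31 and Srm of 21 ribosome biogenesis and MYC targets fell by 0.28. The G2/M list was lower in camera (adjusted p = 0.00613, and adjusted p = 0.396 with an estimated correlation), as was the ribosome list (adjusted p = 0.00394, and adjusted p = 0.241 with an estimated correlation), and neither was called in fry (0.128 and 0.0640), while the S phase list was not called (adjusted p = 0.0581). Without XAV939 replicate 2 the G2/M list had 0.0605, and without XAV939 replicate 1 the S phase list had 0.00424 (0.00380 to 0.486 over the alternatives). More genes fell with other sets of arrays: 5 of 21 in the G2/M list without XAV939 replicate 1, alone or together with CHIR99021 replicate 3, and in the S phase list 2 of 20 with 1 of these arrays left out and 3 without both. Nusap1 lost its call without CHIR99021 replicate 2 (0.0553), Ccne1 without CHIR99021 replicate 1 or 2 (0.0603 to 0.0681), and Srm without any 1 array except CHIR99021 replicate 3 (0.0570 to 0.122).

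A hypothesis was tested that genes next to each other in the genome change together. Among 14468 neighbouring pairs without overlapping genes or similar symbols, 159 changed in the same direction, against a mean of 95.2 (77 to 114) in 10000 permutations of the calls within expression deciles (p = 1e-04, the smallest they can give, adjusted p = 1.5e-04). Pairs that changed in opposite directions numbered 64, below the permutation range of 75 to 111 (mean 92.9). The permutation p of 0.999 tests only for an excess of such pairs. Pairs chosen after their values were seen were Cdx1 and Pdgfrb (1.62 and 0.59), Cyp26a1 and Myof (1.19 and 0.60), Phc1 and Rimklb (-0.93 and -0.85) and Tdgf1 and Lrrc2 (-0.63 and -0.59). A shift of neighbouring genes that single arrays share without any treatment difference was tested as another cause. The rank correlation of neighbours was 0.0755 (0.0598 to 0.0912) in the treatment difference. In the sum of the deviations of CHIR99021 replicate 3 and XAV939 replicate 1 from their groups it was 0.0820 (0.0651 to 0.0978), and 0.0352 in their difference. The sum lay above its permutation range (-0.0141 to 0.0178), so neighbours also moved together without a treatment difference. Yet a shift in the same direction on both arrays cancels in the treatment difference. Only the difference of their deviations enters it, and its 0.0352 was given no interval. The test therefore cannot tell shared regulation of neighbours from shifts of single arrays.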
